A study of Mus musculus with 16 samples.

How the data were processed

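Total RNA from mouse liver was measured on Affymetrix whole-transcript gene arrays. The labels describe 4 genotypes on 1 mouse strain with 4 samples each, 16 arrays in all. The extraction used a Purelink RNA kit, and the targets were labelled with biotin by the whole-transcript sense protocol. Sex, age, time of day, batch and replicate numbers are not given in the sources used here. Replicates are numbered here in the order of the deposited samples. No paired analysis was possible because the labels give no replicate numbers. Whether the 4 samples of a genotype are separate animals is not stated, so p-values measure the spread between these samples.

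The deposited values are log2 signals for each probe set and array, made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the summarisation method, the background correction and the normalization are not given in the sources used here. Values reached down to about 0, with 1.30% to 2.97% of an array's values below 1, and the arrays did not share 1 distribution. The median over all 35556 probe sets of an array lay between 7.20 and 7.51. The number of arrays limits the precision of every value.

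Gene names came from the platform annotation. It gives a gene for 23410 probe sets and several genes for 1621 of these, which were left out because their signal belongs to no single gene. Another 12146 probe sets have no gene listed and were not used. The 21789 probe sets with 1 gene stand for 19938 genes, and 21698 of them matched the RefSeq gene table (assembly GRCm38.p6) by gene ID. That table was used for names and for which genes neighbour each other, and no coordinates are printed because the build behind the arrays is not given in the sources used here.

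A probe set was kept if it reached its array's 40th percentile in at least 4 arrays. Where a gene had several, the probe set with the highest mean over the 16 arrays was taken, which left 13150 genes. Each gene was fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3, with the data.table package in version 1.17.8) with 4 genotype means and 12 residual degrees of freedom. All tests were two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Errors beside fold changes are limma's standard errors (SE), and errors beside group means are standard deviations (SD).

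There were 8 comparisons: each altered genotype against wild type, the double genotype against each single one, the Rassf1a and Sav1 effects averaged over the other gene, and their interaction. Comparisons, their tests, gene lists and the rule for naming genes were fixed before the data were examined, and tests of explanations were written with the data in hand. For a genotype against wild type, the rule names up to 10 higher and 10 lower genes with the largest change among the called genes whose 4 arrays all lie beyond the 4 arrays of the other group. Elsewhere it names up to 5 per direction by size. Where fewer pass, genes with the smallest unadjusted p are named as not passing. Rassf1, Sav1, Tbk1 and every measured beta tubulin are always named, as are up to 4 members of a described list with the smallest p. Models without a proper gene name were counted and not named.

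Of 45 fixed gene lists, 42 had at least 5 measured genes and were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. The same lists were tested with a correlation estimated from the arrays and with fry. The direction p of fry asks whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction. Neither sets the list against other genes.

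Comparisons that share wild-type arrays were set beside 100 simulations of unchanged groups and beside a division of the wild-type arrays into 2 and 2. Signal of Y-linked genes was used to check the mix of sexes. A clock score, the mean of 4 clock genes minus the mean of 9 others that peak at another time, was used to compare clock phase. Correlations across arrays were tested by permutation within genotypes, and small group differences by exact permutation.

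The pipeline was tested on simulated data with 13150 genes, 200 of them changed, in 20 runs. For Rassf1a-/- against wild type it recovered 17.4% of genes changed by 0.5 on the log2 scale, 74.2% of those changed by 1 and 97.7% of those changed by 2, with 4.81% false calls. For the averaged Rassf1a effect the shares were 48.2%, 93.3% and 99.1%, with 4.73% false calls. A list shifted by 0.5 was found in 20 of 20 runs, with 1 false list call in all runs. The simulated genes varied independently, and the simulated arrays of a group did not differ in sex or clock phase. These rates of false gene and list calls therefore do not carry over to the real arrays or to lists of correlated genes.

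Alternatives were no filter, a stricter filter at the 60th percentile, the mean of a gene's probe sets, all probe sets, only the compared genotypes, eBayes with trend and robust, quantile normalization, median centring, array weights, a 1.5-fold minimum, an adjusted p under 0.10, the Y-linked mean as a covariate, and leaving out each array in turn. Leaving out the 5 arrays of high Y-linked signal was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.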

Results

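Liver gene expression was measured in mice of 1 strain and 4 genotypes, with 4 arrays each: wild type, Rassf1a-/-, Sav1+/- and Rassf1a-/- Sav1+/-. Rassf1a is an isoform of Rassf1, a tumour suppressor gene silenced in many cancers, and Sav1 encodes the adaptor of the Hippo pathway kinases. The study's title links Rassf1a loss to liver tumours, to the kinase Tbk1 and to beta tubulin expression. The comparisons ask which liver transcripts differ with the loss of Rassf1a, with the loss of 1 Sav1 copy and with their combination. Across genes, which are not independent replicates, arrays of 1 genotype correlated at Pearson r of 0.889 to 0.984. The median was 0.948, against 0.934 for arrays of different genotypes.

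The genes targeted in these mice were examined as a check on the labels. Sav1 (probe set 10400795) averaged 8.53 ± 0.11 in wild-type, 8.61 ± 0.14 in Rassf1a-/-, 7.64 ± 0.37 in Sav1+/- and 7.65 ± 0.27 in Rassf1a-/- Sav1+/- livers (log2 units, SD, n = 4 each). Averaged over the Rassf1a genotypes, Sav1 fell by 0.93 on the log2 scale with 1 copy lost (SE 0.12, 1.90-fold, adjusted p = 0.0113), and all 8 Sav1+/- arrays lay below all 8 others. Sav1 was -0.90 in Sav1+/- livers against wild type without passing (SE 0.17, adjusted p = 0.110, but 0.0275 without Sav1+/- replicate 2 and 0.0255 with array weights) and fell by 0.88 in the double genotype (adjusted p = 0.0230). That call held in 10 of the 16 fits that left out 1 array. It was lost without a filter (0.0510), with the Y-linked mean as a covariate (0.0803) and without the 5 arrays of high Y-linked signal (0.283). The covariate also ended the averaged call (-0.84, adjusted p = 0.0596), as did leaving out the 5 arrays of high Y-linked signal (0.732). Rassf1 (probe set 10588669) averaged 7.44 ± 0.17, 7.20 ± 0.20, 7.52 ± 0.50 and 7.56 ± 0.10 in the same order. Its difference from wild type was -0.24 in Rassf1a-/- livers (SE 0.20, adjusted p = 0.667) and +0.12 in the double genotype (adjusted p = 0.859). A probe set over exons shared by the Rassf1 isoforms may not show the loss of the 1A form, so these values check nothing about the Rassf1a genotype.

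Transcripts of the sex chromosomes divided the arrays without regard to the stated groups. In 5 arrays the Y-linked genes averaged 8.87 or more and Xist, the transcript that silences an X chromosome in females, was at most 4.31, while the other 11 had a Y-linked mean of at most 4.17 and Xist of at least 10.3. None of the 4 wild-type arrays was among the 5, against 1 Rassf1a-/- (replicate 2), 2 Sav1+/- (replicates 3 and 4) and 2 Rassf1a-/- Sav1+/- arrays (replicates 1 and 2). The first principal component, with 35.0% of the variance, put a gap of 44.6 between the 5 and the 11, against ranges of 6.24 and 9.72 within them. Within genotypes 619 genes followed the Y-linked mean, 222 higher and 397 lower. They include 2 of the 92 genes called in Rassf1a-/- livers and 8 of the 108 called in the double genotype. Such genes vary within genotypes that mix both kinds of array and are seldom called, so these counts do not exclude an effect of sex.

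**Figure D1:**
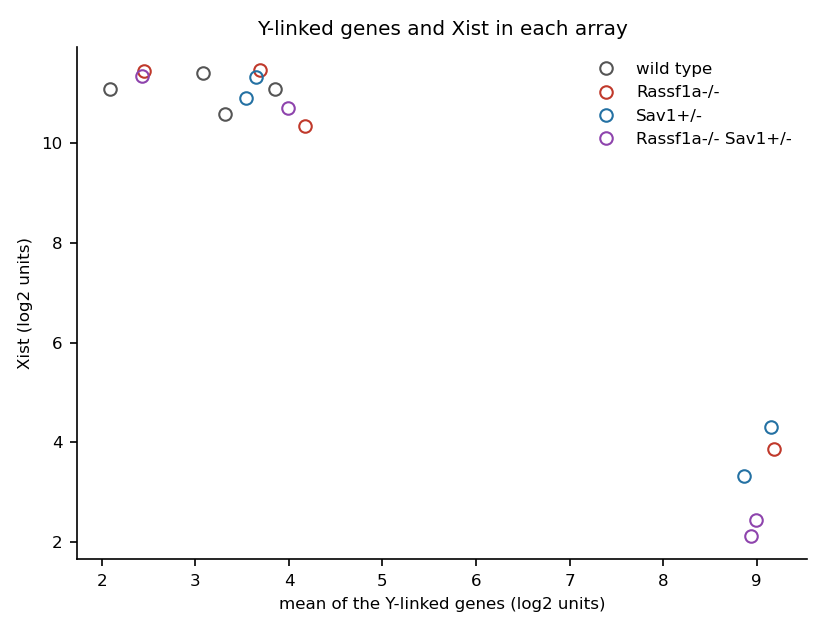
Mean log2 signal of the Y-linked genes (horizontal) against log2 signal of Xist (vertical), 1 point per array, coloured by genotype. The 5 arrays at the lower right, none of them wild type, have a Y-linked mean of at least 8.87, and the 11 others have at most 4.17.

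Rassf1a-/- livers differed from wild-type livers in genes of the circadian clock and in beta tubulins, the fixed gene lists with the smallest p. Arntl, which encodes the clock's activator BMAL1, rose by 3.37 ± 0.34 on the log2 scale (SE, n = 4 per genotype), while Ciart, a repressor in the same loop, fell (-4.16 ± 0.50). Usp2 fell 14.9-fold (-3.90 ± 0.33) and Dbp, a clock output factor, by 3.17 on the log2 scale (SE 0.46), while Per3 was lower by 2.76 (SE 0.32). Among beta tubulins, Tubb2a rose 3.97-fold (+1.99 ± 0.27, adjusted p = 0.00103) and Tubb2b by 1.85 on the log2 scale (SE 0.28, adjusted p = 0.00249). Genes are named here and in the next paragraph only if their 4 arrays lay beyond the 4 of wild type, as the naming rule requires. Arntl (6.71), Tubb2b (6.78), Gask1a (7.28) and Tmie (6.83) in wild-type livers and Ciart (6.02) and Per3 (7.20) in Rassf1a-/- livers averaged below the level of the filter on dim probe sets (7.16 to 7.44 over the arrays), so the sizes of their changes are uncertain.

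Further genes higher in Rassf1a-/- livers were Gask1a (+2.14), the choline kinase gene Chka (+1.78, 3.43-fold), Ndrg1 (+1.67 ± 0.15, 3.17-fold, adjusted p = 3.5e-05), Denn2b (+1.54), Tmie (+1.5), Ppp1r3c (+1.46), whose product targets a phosphatase to glycogen, and Clpx (+1.42), which encodes a subunit of a mitochondrial protease. Lower genes were Wee1 (-2.45, 5.45-fold), the rhythmic Noct (-2.31, 4.95-fold), Per2 (-2.22), Coq10b (-2.15), Alas1 (-2.11), which encodes a rate-limiting enzyme of haem synthesis, and Per1 (-1.85). Noct passed in 7 and Per1 in 11 of the 16 fits without 1 array, with adjusted p up to 0.152 (Noct without wild-type replicate 3) and 0.0934 (Per1 without Rassf1a-/- replicate 2). The other 18 of these 20 genes, beta tubulins and clock genes included, passed in all 16. Noct also failed without a filter (0.0730) and with trend and robust (0.0986).

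In total 92 of 13150 genes were called in Rassf1a-/- livers, 57 higher and 35 lower. Groups did not overlap in 1429 genes (10.9%), against 2.86% by chance. The count was 56, 54 or 58 without wild-type replicate 1, 3 or 4, and 54 or 61 without Rassf1a-/- replicate 1 or 2.

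Of 5 measured beta tubulins, 4 were called higher in Rassf1a-/- livers over all genes and 5 when adjusted over the list alone. Beside Tubb2a and Tubb2b these were Tubb1 (+0.98 ± 0.17, 1.97-fold, adjusted p = 0.00682) and Tubb5 (+0.79 ± 0.14, 1.73-fold, adjusted p = 0.00795), while Tubb6 (+0.53 ± 0.18) had an adjusted p of 0.266, or 0.00877 over the list alone. Without the 5 arrays of high Y-linked signal Tubb1 (+0.99, adjusted p = 0.0682) and Tubb5 (+0.73, adjusted p = 0.0909) did not pass. The list shift had a camera adjusted p of 3.79e-11 and of 0.0488 with an estimated correlation. The study's title names this family, which may have been chosen from these samples, so the list counts are not independent evidence. Tubb3 (+0.04) and Tubb4a (+0.04) lay below the signal filter, and Tubb4b has no probe set of its own. Tubb2a and Tubb2b are near-identical paralogs, so how much of each signal belongs to which gene is uncertain. Of 8 other tubulins none was called, the nearest being Tuba4a (+0.48 ± 0.17, adjusted p = 0.286). Tbk1 averaged 8.25 ± 0.20 in wild-type and 8.31 ± 0.12 in Rassf1a-/- livers (SD, n = 4), a difference of +0.06 ± 0.26 (adjusted p = 0.936) that turned to -0.00472 without wild-type replicate 2.

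**Figure D2:**
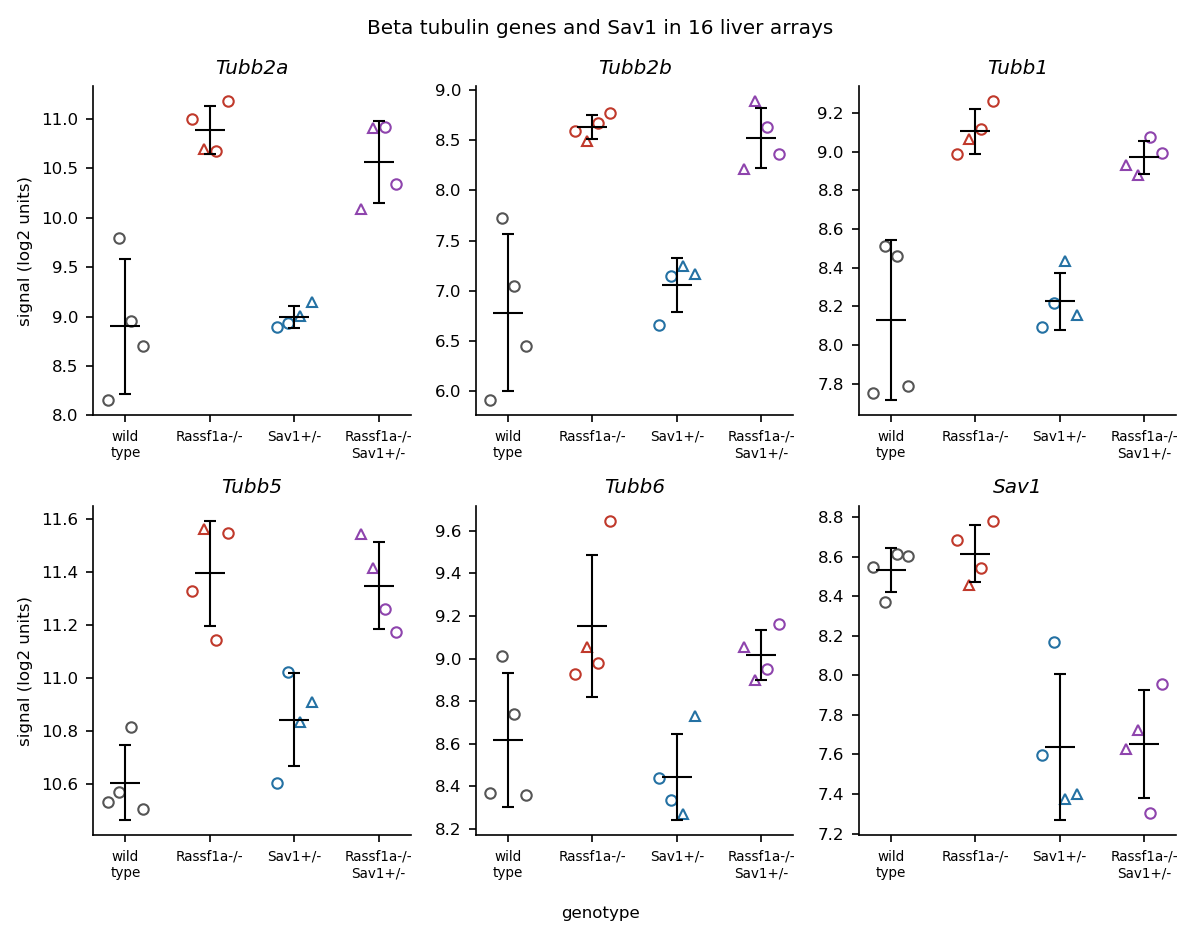
Log2 signal of 5 beta tubulin genes and Sav1 by genotype, 1 symbol per array (triangles mark the 5 arrays of high Y-linked signal), with mean and SD of the 4 arrays in black. Tubb2a lies between 10.68 and 11.18 in the Rassf1a-/- arrays and between 8.15 and 9.79 in wild type.

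Of 16 measured clock genes, 2 were called higher and 8 lower in Rassf1a-/- livers (4 and 11 adjusted over the list alone; camera adjusted p = 4.06e-09, or 0.304 with an estimated correlation). Members move in both directions, and fry's mixed adjusted p was 1.01e-05. Among genes of Wnt-responsive, pericentral hepatocytes, 2 of 18 were lower, the Wnt inhibitor Notum (-0.88 ± 0.17, adjusted p = 0.0154) and Slc1a2 (-0.90 ± 0.19, adjusted p = 0.0352), and the list shifted down (0.00858, or 0.666 with an estimated correlation; 0.0817 without Rassf1a-/- replicate 3). Thrsp, a regulator of fat synthesis, fell by 1.48 on the log2 scale (SE 0.25, adjusted p = 0.00678), while its list of 19 had a median of +0.04, a mean of -0.02 and no shift (0.725). Of 18 genes of ER stress and ATF4 targets, called unfolded protein response genes below, Sdf2l1 rose (+1.30 ± 0.25) and Herpud1 fell (-0.82 ± 0.15).

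Several lists shifted without a called member. Interferon-stimulated genes were positive in 18 of 21 (camera adjusted p = 0.00597), with Cmpk2 (+0.97) and Oasl1 (+0.68) passing over the list alone. Acute phase genes were negative in 20 of 21 (0.0121) and immediate early genes in 9 of 11 (median -0.36, 0.00597). Genes of fatty acid oxidation and PPAR alpha targets, 1 list called fatty acid oxidation below, were lower (0.0496). Ribosomal (0.00941) and respiratory chain genes (0.0122) were higher, and neighbours of Rassf1 lower (0.0121), among them Gnat1 (-1.26, 0.0103 over the list alone). With an estimated correlation these adjusted p lay between 0.309 and 0.902. Over 22 other settings acute phase genes passed in 18 (up to 0.302 without wild-type replicate 1) and respiratory chain genes in 17. Fatty acid oxidation passed in 11, with 0.532 under the Y-linked covariate. Without the 5 high-Y arrays it failed (0.102), as did acute phase (0.0908), ribosomal (0.115) and respiratory chain genes (0.141) and neighbours of Rassf1 (0.0892), and interferon-stimulated genes failed with the stricter filter (0.0848). Neither the 30 Hippo pathway components (0.402), the 22 YAP targets (0.867), the 14 cell cycle genes (0.467) nor the 12 partners of Tbk1 (0.638) held a called gene. Of 56 list calls over the 8 comparisons, the beta tubulins in Rassf1a-/- livers were the only one that held with an estimated correlation.

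Sav1+/- livers held no gene that passed against wild type. The smallest adjusted p of limma was 0.0748, and 1203 genes had an unadjusted p under 0.05. The lowest p values belonged to the amino acid transporter gene Slc43a1 (-1.17 ± 0.18, 2.24-fold) and to Alpl, which encodes alkaline phosphatase (-0.99 ± 0.16, 1.98-fold). Next among lower genes came Rhbdd2 (-0.83), Nr1i2 (-0.70), which encodes the xenobiotic receptor PXR, and Wnt5b (-1.0). Values were higher for Gmip (+0.63), the interferon-induced Ifi27l2a (+1.27), Dpep2 (+2.27), Pdcd10 (+0.61) and Ly96 (+0.73). Slc43a1 passed without wild-type replicate 3 (adjusted p = 0.00216) or Sav1+/- replicate 2 (0.0387), and Alpl without Sav1+/- replicate 2 (0.0427) or Rassf1a-/- Sav1+/- replicate 3 (0.0105). Both also passed with the stricter filter (each 0.0422), with array weights (each 0.0259) and with trend and robust (0.0254 and 0.0408), the last of which passed Rhbdd2 as well (0.0495). Leaving out Sav1+/- replicate 2 gave 6 calls in all, and leaving out wild-type replicate 3 or Rassf1a-/- Sav1+/- replicate 3 gave 1. Groups did not overlap in 616 genes (4.68%), against 2.86% by chance.

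Beta tubulins were not called in Sav1+/- livers (Tubb2a +0.10, Tubb2b +0.27, Tubb1 +0.10, Tubb5 +0.24, Tubb6 -0.17), and Tbk1 was +0.27 ± 0.26. The sign turned to -0.15 for Tubb2a and -0.02 for Tubb2b without wild-type replicate 1. For Tubb1 it turned to -0.03 and -0.02 without wild-type replicate 1 or 4, and for Tbk1 to -0.06 without Sav1+/- replicate 2. Interferon-stimulated genes were positive in 20 of 21, with 4 passing over the list alone, among them Ifi27l2a and Ifit1 (+1.04), and a camera adjusted p of 9.26e-12 (0.593 with an estimated correlation). Fatty acid oxidation genes and PPAR alpha targets were lower (4.26e-06, estimated 0.593), with Acot1 (-1.34) passing over the list alone. Kupffer cell and macrophage markers were positive in 15 of 16 (0.00124, estimated 0.975) and cell cycle genes in 11 of 14 (0.0371, estimated 0.856). The Kupffer cell shift was lost without Sav1+/- replicate 2 (0.308). The cell cycle shift passed in 16 of 21 other settings, failing after quantile normalization and without wild-type replicate 1 or 4 or Sav1+/- replicate 1 or 2, with adjusted p up to 0.288. Male-biased liver genes had a median of +1.71 (3.06e-08) and female-biased genes of -2.27 (0.00701) in this comparison of 2 high-Y arrays in 4 with none in 4. With an estimated correlation the adjusted p were 0.856 and 0.975. With the Y-linked mean as a covariate the male-biased shift was lost (0.524), and the female-biased shift turned upward (0.00662).

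Rassf1a-/- Sav1+/- livers differed from wild type in clock genes and beta tubulins among others. Arntl (+3.01 ± 0.34) and Tubb2b (+1.74 ± 0.28) rose, and Tubb2a rose 3.17-fold (+1.66 ± 0.27), while Ciart (-4.02 ± 0.50) and Wee1 (-2.88 ± 0.34) fell and Usp2 fell 11.8-fold (-3.57 ± 0.33). Ciart (6.17), Wee1 (7.02) and Unc79 (5.21) averaged below the level of the filter on dim probe sets in these livers. So did Arntl (6.71) and Tubb2b (6.78) in wild-type livers, and the sizes of all these changes are uncertain. Other higher genes were Chka (+1.65), Ndrg1 (+1.61), the actin regulator gene Eps8l2 (+1.5), the manganese exporter gene Slc30a10 (+1.44), Clock (+1.37), Denn2b (+1.33) and Clpx (+1.29). Further lower genes were Unc79 (-2.71), Per3 (-2.29), Dbp (-2.19), the growth factor gene Nrg4 (-1.92), Coq10b (-1.89), Thrsp (-1.83 ± 0.25, 3.57-fold) and the nicotinamide riboside kinase gene Nmrk1 (-1.72). Of these 20 genes, Eps8l2 passed in 12, Unc79 in 8, Dbp in 11 and Nrg4 in 9 of the 16 fits without 1 array, with adjusted p up to 0.165 (Unc79 without Rassf1a-/- Sav1+/- replicate 2). The others passed in all 16. Dbp was lost with the Y-linked covariate (0.0531), without a filter (0.0654), with only these genotypes fitted (0.0800) and with trend and robust (0.0647). Unc79 (0.0736 and 0.0627) and Nrg4 (0.0678 and 0.0573) were lost without a filter and with trend and robust, and without the 5 high-Y arrays only Arntl, Ndrg1, Usp2, Wee1 and Thrsp of the 20 passed.

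In all, 108 genes were called in the double genotype, 44 higher and 64 lower, and groups did not overlap in 1416 genes (10.8%, against 2.86% by chance). Without wild-type replicates 1 to 4 the count was 55, 58, 59 and 39, and without replicates 1, 2 or 3 of the double genotype 53, 40 and 61. It was 173 without replicate 4, and 209 or 172 without Sav1+/- replicate 1 or 2. Among the 11 arrays of low Y-linked signal all 108 genes kept their direction but 6 genes were called, 5 of them shared. The 108 genes were selected with these same 11 arrays included, so their kept direction is not independent evidence. Standard errors there were 1.29 times as large at the median and fold changes 0.929 times.

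Of 5 beta tubulins, 4 were called higher in the double genotype (5 adjusted over the list alone, a family the study's title names and not independent evidence; camera adjusted p = 3.42e-08, or 0.161 with an estimated correlation). Tubb1 (+0.84, adjusted p = 0.0230) and Tubb5 (+0.74, adjusted p = 0.0148) each passed in 11 of the 16 fits without 1 array, with adjusted p up to 0.0910 (Tubb1 without wild-type replicate 4). With the Y-linked covariate Tubb1 had 0.0506 and Tubb5 0.0617, Tubb1 also failed without a filter (0.0510) and with only these genotypes fitted (0.0705), and without the 5 high-Y arrays no beta tubulin passed, at changes of +1.73 (Tubb2a, SE 0.35), +1.71 (Tubb2b, SE 0.37), +0.91 (Tubb1, SE 0.23) and +0.61 (Tubb5, SE 0.19). Tubb6 was +0.40 (adjusted p = 0.344) and Tbk1 -0.02 ± 0.26. The sign for Tbk1 was positive without wild-type replicate 4 (+0.08) or replicate 3 of the double genotype (+0.15). Of 16 clock genes 3 were higher and 8 lower (3 and 11 over the list alone; 2.02e-08, estimated 0.342). Fatty acid oxidation genes and PPAR alpha targets shifted down (2.18e-05, estimated 0.481) with Angptl4 called lower (-0.91 ± 0.20, adjusted p = 0.0403). Unfolded protein response genes were positive in 17 of 18 (8.49e-04, estimated 0.911), while ribosomal genes were negative in 15 of 16 (2.91e-05, estimated 0.694), with Rps14 (-0.69) among 4 passing over the list alone. Respiratory chain genes shifted down (0.00134, estimated 0.481; 0.0540 after quantile normalization). Without the high-Y arrays the unfolded protein response genes had 0.0767. Male-biased genes were higher (4.99e-04) and female-biased genes lower (0.00116), both 0.911 with an estimated correlation, as 2 of the 4 double-genotype arrays were high in Y-linked signal. With the Y-linked covariate both shifts were lost (each 0.398), and the direction of the female-biased genes turned upward, as it did without the high-Y arrays (0.224). No YAP target among 22 was called (0.211).

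Rassf1a-/- and double-genotype livers shared 30 higher and 18 lower calls, against 0.191 and 0.170 for independent lists. Their fold changes correlated across genes at r = 0.587 with a covariance of 0.0624. Because both use the same wild-type arrays, unchanged groups already give r = 0.491 and 0.0314 in simulation, a covariance difference of 0.0310. With the wild-type arrays divided into 2 and 2, a median of 12 calls was shared (9 to 18 over 6 divisions) at a median r of 0.404. Sav1+/- and double-genotype livers, each against all wild-type arrays, correlated more strongly (r = 0.636, 0.498 in simulation, covariance difference 0.0369). Both genotypes held 2 high-Y arrays and wild type 0, a sex mix that the simulation lacks. The excess can therefore not be assigned to Sav1 loss. A pair without common arrays, Rassf1a-/- against wild type and the double genotype against Sav1+/-, shared 25 higher and 9 lower calls (0.381 and 0.0586 for independent lists). Its r of 0.312 was above the -0.00785 of the simulation but within the range of another pair without common arrays. Rassf1a-/- and Sav1+/- livers, each against 2 separate wild-type arrays, gave a median r of 0.209 (0.0433 to 0.364 over 6 divisions) and 0 shared calls. The 34 shared genes include Arntl, Chka, Tubb2a, Tubb2b, Tubb1, Ndrg1, Gldc and Amt as higher and Ciart, Usp2, Dbp, Per3, Wee1, Tef and Thrsp as lower. Both comparisons that call these genes take residual variances from the same fit of all arrays, so their calls are not independent. Fitted on its own genotypes alone, the double genotype against Sav1+/- lost nearly all calls, as given below. Arntl passed there, but Tubb2a and Usp2 (adjusted p = 0.0511 each), Chka and Ciart (0.0721 each), Wee1 (0.118) and Dbp (0.239) did not.

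**Figure D3:**
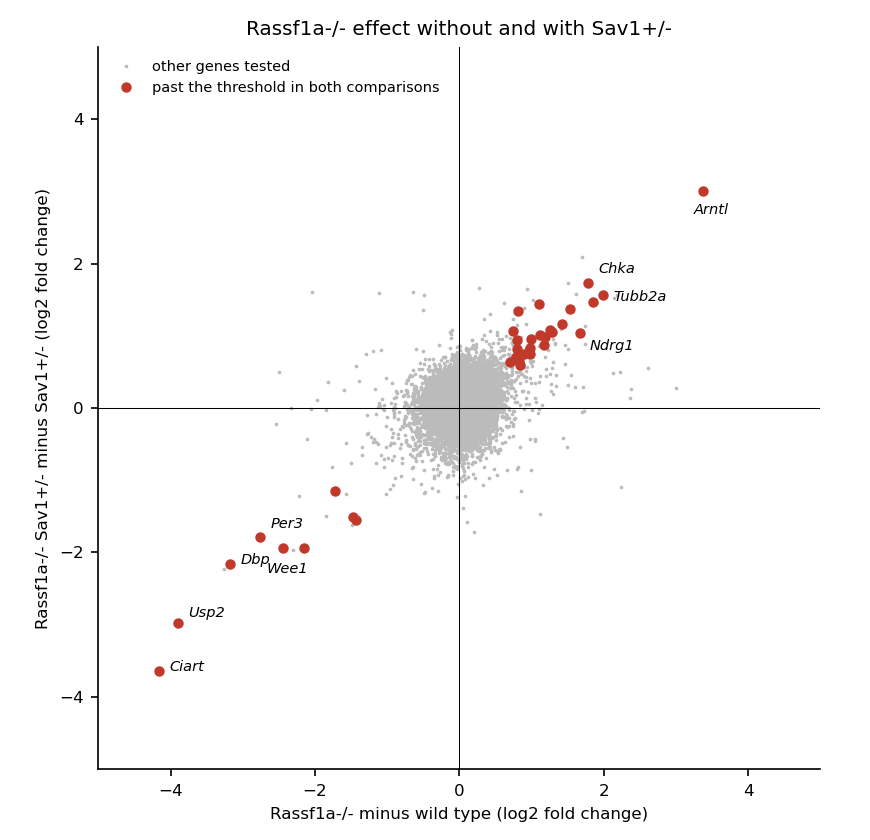
Log2 fold change of each of 13150 genes in Rassf1a-/- against wild-type livers (horizontal) and in Rassf1a-/- Sav1+/- against Sav1+/- livers (vertical), which share no arrays. The 34 red points passed the threshold in both, 25 higher and 9 lower, and none in opposite directions. Both comparisons take residual variances from the same fit of all arrays, so the shared calls are not independent.

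Between the double genotype and Rassf1a-/- livers 1 gene was called, Lrrc51, lower by 1.09 on the log2 scale (SE 0.16, adjusted p = 0.0329), to an average of 7.14 that lies below the level of the filter on dim probe sets. It passed in 5 of the 16 fits without 1 array and in neither the fit without a filter (0.0897) nor that of these 2 genotypes alone (0.14) nor after quantile normalization (0.0558). Pacc1 (+0.58), Mocs3 (+0.61) and Tnfrsf19 (+1.03) did not pass, though all 3 did with array weights (0.00428, 0.0226 and 0.00879), and Pacc1 without Sav1+/- replicate 2 (0.0360) or replicate 4 of the double genotype (0.0367). Sav1 itself was -0.96 (adjusted p = 0.0613). At an unadjusted p under 0.05 there were 1934 genes, and groups did not overlap in 1291 (9.82%, against 2.86% by chance). No gene was called without any 1 of the wild-type or Rassf1a-/- arrays or of replicates 1 to 3 of the double genotype, whereas 123 were called without Sav1+/- replicate 2 and 209 without replicate 4 of the double genotype.

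By camera at its preset correlation, transcripts of the ribosome and the respiratory chain were lower as groups in the double genotype than in Rassf1a-/- livers. List shifts between the double genotype and either single genotype, and in the interaction, were not followed singly under other settings. Ribosomal genes were negative in 16 of 16, with a median of -0.40 and 11 passing over the list alone (camera adjusted p = 2.73e-11, estimated 0.277; fry 0.00968), Rps18 (-0.63) and Rpl8 (-0.49) among those with the smallest p. Respiratory chain genes were negative in 21 of 23 with a median of -0.28 and 10 passing over the list alone (4.49e-08, estimated 0.14; fry 0.00313), led by Ndufa1 (-0.75) and Ndufa2 (-0.59). Acute phase genes, pericentral genes such as Lgr5 (+1.21) and Kupffer cell markers such as Marco (+1.93) shifted up (each 0.0375, estimated 0.991), with no gene called over all genes.

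Between the double genotype and Sav1+/- livers 110 genes differed, 88 higher and 22 lower without Rassf1a. Arntl rose (+3.01 ± 0.34), Chka 3.32-fold (+1.73 ± 0.24) and Cyp8b1, which shapes the bile acid pool, 3.14-fold (+1.65 ± 0.26, adjusted p = 0.00696). Tubb2a rose 2.97-fold (+1.57 ± 0.27) and Celsr1 2.82-fold (+1.5, SE 0.24). Ciart (-3.64), Usp2 (-2.98), Dbp (-2.17), Wee1 (-1.94) and Coq10b (-1.94) fell. Arntl (6.71) in Sav1+/- livers and Ciart (6.17) and Wee1 (7.02) in the double genotype averaged below the level of the filter on dim probe sets, as did Tubb2b (7.06 in Sav1+/- livers), so the sizes of their changes are uncertain. Tubb2a had an adjusted p of 0.0577 without replicate 2 of the double genotype, and Dbp passed in 8 of the 16 fits. Dbp passed in 4 of 10 other settings (0.0717 without a filter, 0.0701 with trend and robust, 0.0510 after median centring), and with array weights Dbp (0.0800), Tubb2a (0.0641) and Cyp8b1 (0.0570) did not pass. Of 5 beta tubulins 3 were higher, Tubb2b (+1.47) and Tubb1 (+0.74) beside Tubb2a, and 5 over the list alone in this family, which the title names (2.18e-06, estimated 0.227). Clock genes held 1 higher and 6 lower calls (3 and 10 over the list alone; 7.74e-10, estimated 0.227). Interferon-stimulated genes shifted down (9.97e-05, estimated 0.937) with Ifi27l2a called lower (-1.58 ± 0.26, adjusted p = 0.00867), and so did cell cycle (0.00621, estimated 0.589) and ribosomal genes (4.02e-05, estimated 0.872), while unfolded protein response genes shifted up (0.00621, estimated 0.937). Partners of Tbk1 did not shift (0.558), though Ikbke (+0.63), Sqstm1 (+0.35) and Ticam1 (+0.50) passed over the list alone (each 0.0389).

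The count of 110 was sensitive to single arrays. It was 66 or 67 without Rassf1a-/- replicate 1 or 4, 62 or 59 without Sav1+/- replicate 1 or 3, and 70, 27 or 42 without replicate 1, 2 or 3 of the double genotype. Without Sav1+/- replicate 2 it was 479. At 2 high-Y arrays in each genotype the sex mix was equal, and non-overlapping genes numbered 849 (6.46%, against 2.86% by chance). Fitted on these 8 arrays alone the comparison gave 1 call, and without the high-Y arrays 0.

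Averaged over the Sav1 genotypes, 8 arrays against 8, 293 genes differed between the Rassf1a states, 231 higher and 62 lower without Rassf1a. Arntl (+3.19 ± 0.24), the dynein gene Dnaic1 (+1.89 ± 0.43, adjusted p = 0.0238), the drug-metabolizing Cyp2b10 (+1.88 ± 0.46, adjusted p = 0.0379) and Gask1a (+1.83 ± 0.27) rose. Ciart (-3.90 ± 0.36), Per3 (-2.27 ± 0.23) and Wee1 (-2.19 ± 0.24) fell, Usp2 fell 10.8-fold (-3.44 ± 0.23) and Dbp 6.36-fold (-2.67 ± 0.33). In both genotypes with Rassf1a, Dnaic1 (5.47 in wild type), Arntl (6.71) and Gask1a (7.28) averaged below the level of the filter on dim probe sets, as did Ciart in both genotypes without it (6.02 and 6.17), Per3 in Rassf1a-/- livers (7.20) and Wee1 in the double genotype (7.02), so the sizes of their changes are uncertain. Dnaic1 was also below that level in Rassf1a-/- livers (7.17). It passed in 10 and Cyp2b10 in 4 of the 16 fits without 1 array, and with trend and robust neither did (0.0530 and 0.0858). Dnaic1 also failed without the 5 high-Y arrays (0.146), and Cyp2b10 without a filter (0.0676). The count was 192 without wild-type replicate 3 or Rassf1a-/- replicate 1 and 572 without Sav1+/- replicate 2. Among the 11 arrays of low Y-linked signal all 293 kept their direction, 80 genes were called and 72 were shared. As these 11 arrays also helped to select the 293, the kept direction is not independent evidence.

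All 5 measured beta tubulins were higher in the averaged comparison, over all genes as well as adjusted over the list alone, again in a family the title names. Tubb2a (probe set 10408610) rose 3.43-fold (+1.78 ± 0.19, adjusted p = 3.81e-05), Tubb2b (10408613) by 1.66 on the log2 scale (SE 0.20; of uncertain size, as it averaged 6.78 and 7.06, below the level of the filter on dim probe sets, in the genotypes with Rassf1a), Tubb1 (10479154) 1.82-fold (+0.86 ± 0.12), Tubb5 (10450605) 1.56-fold (+0.65 ± 0.10, adjusted p = 0.00118) and Tubb6 (10456400) 1.47-fold (+0.55 ± 0.13, adjusted p = 0.0267). Tubb6 passed in 10 of the 16 fits without 1 array, with adjusted p up to 0.0645 (without wild-type replicate 1), and the other 4 in all. Without a filter Tubb6 had 0.0548, and without the 5 high-Y arrays Tubb5 (+0.57, adjusted p = 0.0954) and Tubb6 (+0.62, adjusted p = 0.157) did not pass. The camera adjusted p was 4.67e-11, or 0.0557 with an estimated correlation. Tuba4a was the only 1 of 8 other tubulins called (+0.54 ± 0.12, adjusted p = 0.0205; list 0.293). Tbk1 (probe set 10372853) was -0.11 ± 0.18 (adjusted p = 0.805) and turned to +0.05 without Sav1+/- replicate 2.

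Clock genes made up 13 of the 293 calls, 3 higher and 10 lower of 16 measured (4 and 11 over the list alone; camera adjusted p = 6.90e-12, or 0.131 with an estimated correlation). Beside those above these were Clock (+1.01) and Nfil3 (+0.82) as higher and Per2 (-1.71), Per1 (-1.67), Tef (-1.44), Bhlhe40 (-0.82) and Nr1d2 (-0.67) as lower, while Hlf (-0.36), Nr1d1 (+0.40) and Cry2 (-0.21) did not pass. The clock score averaged -2.43 ± 0.45 in wild-type and -2.36 ± 0.47 in Sav1+/- arrays, and 0.81 ± 0.18 in Rassf1a-/- and 0.26 ± 0.93 in double-genotype arrays (SD, n = 4 each). The states did not overlap, the lowest score without Rassf1a being -0.746 (double-genotype replicate 4) and the highest other -1.79 (wild-type replicate 2). The beta tubulin and clock differences therefore fall between the same arrays.

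**Figure D4:**
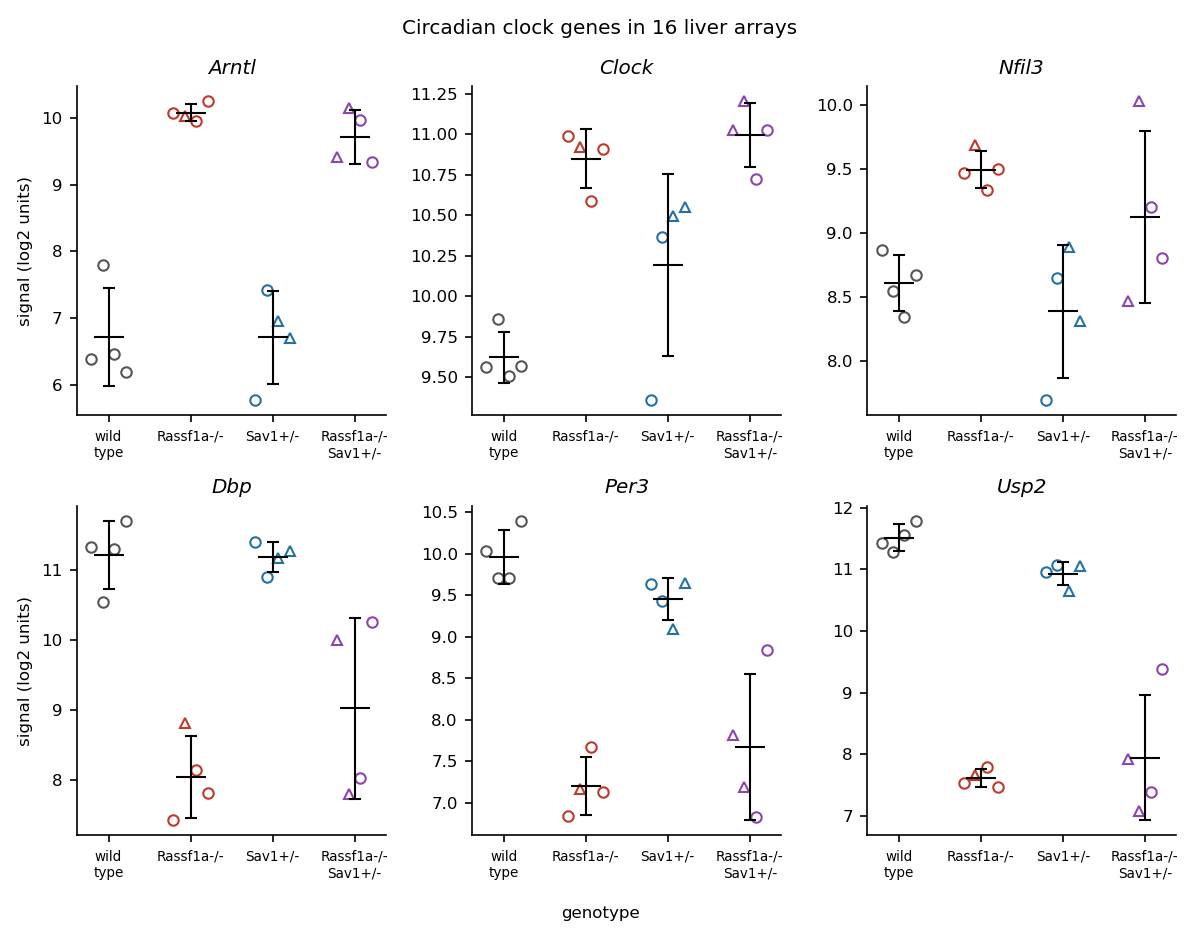
Log2 signal of 6 clock genes by genotype, 1 symbol per array (triangles mark the 5 arrays of high Y-linked signal), with mean and SD of the 4 arrays in black. Arntl lies between 9.34 and 10.25 in the arrays of both Rassf1a-/- genotypes and between 5.77 and 7.80 in the others.

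Metabolic genes outside the list of clock genes changed singly in the averaged comparison. Whether they follow the clock difference between the same arrays was not tested. Thrsp fell by 1.49 on the log2 scale (SE 0.18, adjusted p = 1.2e-04) and Angptl4, an inhibitor of lipoprotein lipase, by 0.79, while Pdk4 (+1.14), which restrains glucose oxidation, Cyp8b1 (+1.30 ± 0.19, adjusted p = 8.1e-04) and Hsd3b7 (+0.46), both of bile acid synthesis, rose. The chaperone gene Hspb1 (+1.04), Map1s (+0.51), which links microtubules to autophagy, and Hal (+0.48) were higher, and Dnaja1 (-0.43) and Ifi27l2a (-0.73) lower. Ifi27l2a was +0.11 in Rassf1a-/- against wild-type livers (adjusted p = 0.878) and -1.58 in double-genotype against Sav1+/- livers. The lists holding these genes did not shift (camera adjusted p of 0.312 to 0.946), and for heat shock genes the median was positive (+0.13) while the test pointed down. Unfolded protein response genes did, with Sdf2l1 (+0.97) and Atf5 (+0.45) higher, Herpud1 (-0.55) lower and 16 of 18 positive (7 higher and 1 lower over the list alone; 0.00438, estimated 0.982). Immediate early genes (0.00949, estimated 0.694) and cell cycle genes (0.0303, estimated 0.731) shifted down without a called member. The cell cycle shift passed in 12 of 21 other settings, among them 8 of the 16 fits without 1 array, with adjusted p up to 0.0929. Hippo components (0.517), YAP targets (0.916) and partners of Tbk1 (0.414) did not shift, and none of their genes was called over all genes. Adjusted over the list alone, 3 of the 12 partners of Tbk1 passed: Ikbke (+0.53, 0.0257), which encodes a kinase related to Tbk1, Sqstm1 (+0.27, 0.0257) and Ticam1 (+0.31, 0.0462).

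Averaged over the Rassf1a genotypes, 3 genes were lower in Sav1+/- livers and none higher. Beside Sav1 itself these were Wnt5b, a Wnt ligand gene (-0.83 ± 0.13, adjusted p = 0.0480), and the autophagy protease gene Atg4d (-0.53 ± 0.09, adjusted p = 0.0480). Wnt5b passed in 4 and Atg4d in 2 of the 16 fits without 1 array, and Sav1 in all. Wnt5b averaged 6.94 in Sav1+/- and 7.13 in double-genotype livers, below the level of the filter on dim probe sets. With 4 high-Y arrays on the Sav1+/- side and 1 on the other, no gene passed with the Y-linked mean as a covariate (Sav1 0.0596, Wnt5b 0.114, Atg4d 0.134) or without the high-Y arrays. Its list of 30 Hippo components had a median of +0.09, a mean of -0.02 and no shift (0.811). Gmip (+0.41), Dpep2 (+1.51) and Pik3ap1 (+0.57) did not pass, though Gmip had an adjusted p of 0.0479 without replicate 4 of the double genotype and Pik3ap1 0.0444 without Sav1+/- replicate 1. With array weights all 3 passed (0.0107, 0.00858 and 0.00935). At an unadjusted p under 0.05 there were 1948 genes. The count was 1 without wild-type replicate 1, 2 or 4, Rassf1a-/- replicate 1, 3 or 4, Sav1+/- replicate 2, 3 or 4, or replicate 1, 2 or 3 of the double genotype. It was 50 without Sav1+/- replicate 1 and 89 without replicate 4 of the double genotype.

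With 1 Sav1 copy lost, 9 lists shifted in the average although Sav1 was the only called member of any list. Kupffer cell markers were positive in 16 of 16, Marco (+1.39) and Mpeg1 (+0.61) with the smallest p (1.85e-04, estimated 0.861), and T and NK cell markers in 7 of 7 (0.0298, estimated 0.861). Respiratory chain genes were negative in 23 of 23 with 7 passing over the list alone (2.73e-07, estimated 0.172; fry 0.00111), and ribosomal genes in 16 of 16 with 6 (4.09e-06, estimated 0.802). Fatty acid oxidation genes and PPAR alpha targets were lower (4.88e-05, estimated 0.802), among them Acot1 (-1.18) and Cyp4a14 (-2.38), and heat shock genes lower (0.0385, estimated 0.861). Interferon-stimulated genes were positive in 20 of 21 (0.00333, estimated 0.861). Heat shock genes passed in 12 of 22 other settings (9 of 16 fits without 1 array; 0.0536 with the Y-linked covariate, up to 0.129) and T and NK cell markers in 16 of 21 (13 of 16 fits without 1 array; up to 0.209). Interferon-stimulated genes failed without the high-Y arrays (0.0686). Male-biased genes were higher (1.09e-05) and female-biased genes lower (0.00333), both 0.861 with an estimated correlation. With the Y-linked covariate the male-biased shift was lost (0.209) and the female-biased genes turned upward (0.613), and without the high-Y arrays they shifted up (0.00434).

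Whether the effects of Rassf1a and Sav1 add up was tested by their interaction, and no gene passed. The smallest adjusted p of limma was 0.316, with 1236 genes at an unadjusted p under 0.05. Alpl (+1.15 ± 0.23), Slc9a8 (+1.11), Rhbdd2 (+0.97), Lsm1 (-1.0), Sntg2 (-0.90) and Slirp (-0.87) had the smallest p. Alpl was the 1 gene called without replicate 3 of the double genotype (adjusted p = 0.0337). For Tubb2a the interaction was -0.42 ± 0.38 (adjusted p = 0.781), for Arntl -0.36 ± 0.48 and for Tbk1 -0.35 ± 0.37. As groups, interferon-stimulated genes were lower than additivity gives in 18 of 21 (4.24e-09, estimated 0.616) with Ifi27l2a (-1.69) among 4 passing over the list alone. Ribosomal genes were lower in 16 of 16 (4.24e-09, estimated 0.515).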

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

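The Y-linked covariate was fixed before the data were examined, the other tests here were written with the data in hand, and those of time of day and of genes near Rassf1 were chosen only after the result was seen. The 11 arrays of low Y-linked signal were picked from the data.

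Clock genes and beta tubulins differ between the same arrays, and both may follow Rassf1a loss or the hour at which tissue was taken, which the labels do not give. Of 13 clock genes 12 had the sign of 1 common phase shift, Hlf and Cry1 without passing, and Nr1d1 was the exception. The lowest clock score of the arrays without Rassf1a was -0.746 (double-genotype replicate 4) and the highest of the others -1.79, so a change of the clock by genotype and tissue taken at another time of day cannot be told apart. Within genotypes the mean of 5 beta tubulins rose with the clock score over 16 arrays (r = 0.496, permutation p = 0.0177, and rho = 0.597, permutation p = 0.0212). Without the 2 arrays whose clock score deviated most within their genotype, r was 0.542, with wild-type replicate 2 still included. The slope, 0.216 (0.122 without wild-type replicate 2), times the clock difference predicts 0.633 (95% interval -0.10 to 1.37) of the 1.10 observed, so genotype and clock cannot be told apart for beta tubulins either.

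The beta tubulin difference and the calls in Rassf1a-/- Sav1+/- livers might instead reflect sex, as no wild-type array and 2 of the 4 double-genotype arrays had high Y-linked signal. Among the 11 arrays of low Y-linked signal the beta tubulin difference was 1.15 (exact permutation p = 0.00476, 210 permutations). With the Y-linked mean as a covariate 0% of the 108 genes called in the double genotype lost at least 0.5 of their change, and the median ratio of fold changes was 0.956. Standard errors grew 1.09-fold and 53 of the 108 were still called. The first test argues against the sex mix as the source of the beta tubulin difference. The second decides little, because a gene that differs by sex also varies within the genotypes that mix both kinds of array. Such a gene is seldom called, so few of the 108 calls could have lost their change. How far the lost calls come from lower precision or from the adjustment for sex was not separated.

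Divisions of the arrays without regard to genotype show how often chance gives as many calls. The real division of Rassf1a-/- and wild type (92 calls, highest other 0) was 1 of 35, and that of the double genotype and wild type (108, highest other 1) was 1 of 35 as well. Chance can be excluded for both only down to the 1 in 35 that 8 arrays allow. The double genotype and Rassf1a-/- also gave 1 of 35, but with 1 call against a highest other of 0, which does not exclude chance. For Sav1+/- against wild type all 35 of 35 divisions gave at least the real 0 calls (highest other 3).

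For the double genotype against Sav1+/- 2 of 35 divisions gave at least the real 110 calls, and the highest other, 306, put all 4 high-Y arrays on 1 side, so it points to sex as a structure of the samples. Among the 18 divisions with 2 high-Y arrays on each side the highest other was 29, and with the Y-linked covariate 173 genes were called. As 2 of 35 is more than 5 in 100, chance is not excluded for this comparison. The 18 divisions allow no share below 1 in 18, so they cannot exclude it either. For the averaged Rassf1a effect 1 of 100 divisions reached 293, the highest other being 231 with all 5 high-Y arrays on 1 side and 127 among the 73 divisions with the real sex mix. For the averaged Sav1 effect 2 of 100 reached the real 3, fewer than 5 in 100, the highest other being 76 with the same sex mix as the real one. With the covariate 0 genes were called, Sav1 included (adjusted p = 0.0596). For the interaction 100 of 100 divisions gave at least the real 0 calls, as any division must. The highest other, 1504, had the real sex mix (3 and 2 high-Y arrays) and points to some structure of the samples, which was not tested.

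Single arrays outside their group were sought by the Dixon ratio in 248 sets of 4 values, and 17 stood out, where chance alone gives about 1 in 20. They were Gask1a in wild-type replicate 2 (0.891; 7.67 against 7.12 to 7.18), Tubb2b in Sav1+/- replicate 1 (0.833; 6.66 against 7.15 to 7.25), Tmie in double-genotype replicate 1 (0.862), Noct in wild-type replicate 3 (0.857), Slc43a1 in wild-type replicate 3 (0.908) and Rassf1a-/- replicate 2 (0.931), Slc30a10 in Sav1+/- replicate 1 (0.929), Clock in wild-type replicate 2 (0.838) and Sav1+/- replicate 1 (0.846), and Nrg4 in Rassf1a-/- replicate 2 (0.836). Further values were Pik3ap1 in double-genotype replicate 1 (0.985), Atg4d in its replicate 4 (0.897), Slc9a8 in its replicate 2 (0.939), Lsm1 in its replicate 4 (0.934), Slirp in Rassf1a-/- replicate 2 (0.868), Xist in the same array (0.852; 3.87 against 10.34 to 11.47) and the beta tubulin mean in Rassf1a-/- replicate 4 (0.845; 10.08 against 9.72 to 9.77).

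In the Rassf1a by Sav1 interaction 7 lists shifted by camera at its preset correlation. They were interferon-stimulated genes (camera adjusted p = 4.24e-09), ribosomal proteins (4.24e-09), respiratory chain genes (0.00844), neighbours of Rassf1 (0.0170), and acute phase, pericentral and male-biased genes (each 0.0453). None passed with an estimated correlation. High Y-linked signal marked 5 arrays, none of them wild type. The Rassf1a-/- genotype held 1 of them, Sav1+/- 2 and the double genotype 2, so the sex mix does not cancel in the interaction. The shift of male-biased genes can therefore not be assigned to Sav1 loss.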

How the results depend on the processing

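Every alternative but the removal of the 5 high-Y arrays, which was added after the data were seen, was fixed before the data were examined. Counts moved widely with the settings, and the cause was not tested. Directions of the named genes seldom turned, but most of these genes were chosen for large changes or small p in the same arrays. Their kept directions are therefore not independent evidence. Array weights raised most counts several-fold.

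Rassf1a-/- against wild type (92) gave 139 with all probe sets, 190 with only the genotypes compared, 899 with array weights, 166 at an adjusted p under 0.10, 146 with the Y-linked covariate and 59 without the 5 high-Y arrays. Sav1+/- against wild type (0) gave 2 with the stricter filter, 3 with trend and robust, 7 with array weights and 2 under 0.10. The double genotype against wild type (108) gave 56 without a filter, 176 with the stricter filter, 165 with trend and robust, 165 after quantile normalization, 1231 with array weights, 239 under 0.10, 61 with the Y-linked covariate and 6 without the high-Y arrays.

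The double genotype against Rassf1a-/- (1) gave 0 without a filter, with all probe sets, with only the genotypes compared, after quantile normalization and without the high-Y arrays, but 55 with the stricter filter, 68 with trend and robust, 74 after median centring, 1978 with array weights and 181 under 0.10. Against Sav1+/- (110) it gave 53 without a filter, 185 with the stricter filter, 1 with only the genotypes compared, 173 with trend and robust, 50 after centring, 55 with array weights, 295 under 0.10, 173 with the Y-linked covariate and 0 without the high-Y arrays.

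The averaged Rassf1a effect (293) gave 446 with the stricter filter, 802 with array weights, 145 with at least 1.5-fold, 621 under 0.10 and 80 without the high-Y arrays. The averaged Sav1 effect (3) gave 1 without a filter, 19 with the stricter filter, 1 with all probe sets, 18 with trend and robust, 19 after quantile normalization, 1516 with array weights, 80 under 0.10, and 0 with the Y-linked covariate or without the high-Y arrays. The interaction stayed at 0 in every alternative that kept the 16 arrays and without the 5 high-Y arrays.

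In the averaged Rassf1a effect Tubb5 was 0.57 without the high-Y arrays (adjusted p = 0.0954), and Tubb6 0.55 without a filter (0.0548) and 0.62 without the high-Y arrays (0.157). In the averaged Sav1 effect Sav1 was -0.84 with the Y-linked covariate (0.0596) and -0.84 without the high-Y arrays (0.732). Tbk1 in the double genotype turned to 0.0417 with the covariate. Camera called 56 gene list shifts, and 1 with an estimated correlation. Fry, which tests against no change and not against other genes, called 11 lists by direction, all of them among the 56. The overlap of 48 calls was 12 with the wild-type arrays divided.

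Leaving out 1 array at a time gave 54 to 128 calls for Rassf1a-/- against wild type, 0 to 6 for Sav1+/-, 39 to 209 for the double genotype, 0 to 209 against Rassf1a-/-, 27 to 479 against Sav1+/-, 192 to 572 for the averaged Rassf1a effect, 1 to 89 for the averaged Sav1 effect and 0 to 1 for the interaction. The averaged Rassf1a effect on Rassf1 ran from -0.19 to 0.00391, on Tbk1 from -0.20 to 0.0488 and on Tubb6 from 0.47 to 0.62. Against wild type, Tbk1 ran from -0.00472 to 0.15 in Rassf1a-/-, from -0.0551 to 0.45 in Sav1+/- and from -0.13 to 0.15 in double-genotype livers. In Sav1+/- livers the ranges were -0.15 to 0.39 for Tubb2a, -0.0173 to 0.59 for Tubb2b, -0.0292 to 0.22 for Tubb1 and -0.13 to 0.25 for Rassf1.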

Other observations

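The test of genes near Rassf1 was chosen only after the result was seen.

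Sex-biased liver genes differed between the 5 arrays of high Y-linked signal and the 11 others. These averaged 12.66 and 4.47 for the steroid enzyme gene Hsd3b5, 13.12 and 4.64 for Cyp4a12a, 12.62 and 6.89 for Elovl3, and 13.79 and 8.26 for Cyp2d9 (log2 units). The reverse held for A1bg (2.01 and 12.11) and the sulfotransferase genes Sult3a1 (3.51 and 13.13) and Sult2a3 (1.68 and 9.74). Most of the lower values lie under the 25th percentile of the arrays (5.73 to 6.14), so sizes of these differences are not given. These genes were chosen after their values were seen.

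Genes near Rassf1 may differ through variants linked to the targeted locus rather than through loss of the protein. Within 200 genes either side of Rassf1, 6 of 167 tested genes (3.59%) were called in the averaged Rassf1a effect against 287 of 12983 elsewhere (2.21%), an odds ratio of 1.65 (95% interval 0.591 to 3.71, Fisher exact p = 0.280). The 6 are Nicn1 (+0.41), Amt (+0.67), Alas1 (-1.27), Ptpn23 (+0.55), Tmie (+1.16) and Rtp3 (+0.51), lying 39 to 155 genes from Rassf1. With the Y-linked covariate 8 were called (odds ratio 1.83, 95% interval 0.769 to 3.73, Fisher exact p = 0.0941), adding Gnat1 (-0.83) and Manf (+0.55), 12 and 21 genes away. Linked variants and an effect of the genotype cannot be told apart by this test.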
